A study of Caenorhabditis elegans with 9 samples.

How the data were processed

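RNA sequencing libraries of Caenorhabditis elegans at the second larval stage (L2) were grouped by their labels into 3 libraries of wild type VA motor neurons, 3 libraries of VA motor neurons from unc-4 mutants and 3 libraries of whole L2 worms of the N2 strain. VA neurons are cholinergic motor neurons of the ventral nerve cord. Per the labels' protocols, larvae were dissociated and cells that carried a red but not a green reporter, driven by different parts of the unc-4 promoter, were collected by fluorescence-activated sorting, a gate that also takes AVF neurons. Per the labels, the whole worms were frozen over liquid nitrogen rather than sorted, and cDNA was made with a low-input SMART-Seq kit. The sorted and the whole-worm groups thus differ in strain and in handling as well as in cell content. Nothing in the labels says that replicates came from separate cultures, so p-values that compare libraries measure the spread between these samples, which may be technical. The Fisher's exact and permutation p-values below take genes as units and measure no spread between samples.

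The authors deposited 2 tables, 1 for wild type VA neurons against whole worms and 1 for unc-4 against wild type VA neurons. Per the file headers, each table gives a TPM value, the authors' measure of transcript abundance scaled by transcript length and library total, for every library and the mean TPM of each group. TPM values count over all genes of a library, so they share a fixed total and keep no sequencing depth. Depth is therefore unknown here, and no counting interval or detection floor is given. The authors' fold change and their false discovery rate (FDR) p-value stand beside the TPM values, per the file headers. The headers do not say how the fold was computed, and it is read here as a linear ratio. The authors' fold lay above the ratio of mean TPM in the whole-worm table (median difference of log2 values -0.39, ratio minus fold) and below it in the unc-4 table (0.23), and the reason for these offsets was not tested. The genome build was WBcel235, per the submitters' processing notes. The names of the libraries in the labels point to gene expression tracks of the CLC software, which the sources used here do not describe further. The aligner, the counting settings and the test behind the FDR are not given in them.

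Both tables hold only selected genes. All 2349 genes of the whole-worm table and all 214 of the unc-4 table had a fold above 1 and an FDR p-value under 0.05 (largest 0.0500 and 0.0488), and 2 rows of the unc-4 table that name no gene, which hold the sum of the unc-4 means and its share of all TPM, were left out. Genes lower in VA neurons or in the mutant, and genes that did not pass, are not analysed here. As fixed before the data were examined for this case, genes were counted as called by the authors at an FDR under 0.05, and the authors' effect was not tested again. "Listed" below means present in such a table. Gene identifiers matched current symbols for 2315 and 213 genes and the Ensembl release 115 annotation of WBcel235 for 2337 and 214 genes; coordinates come from that annotation. Symbols are those of the tables.

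The 3 libraries of each group were also compared in a fit added after the tables were seen to hold selected genes: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 1) of listed genes with a mean of at least 1 TPM in either group, with Benjamini-Hochberg adjustment. Log2 differences are on that scale, which understates the change of low genes. These genes were selected on the same libraries, so the adjusted p-values are not independent evidence and serve to show how a call rests on single libraries. The fit was also run on values simulated around the higher group's mean, with a pooled spread per gene for both groups. Of 2349 simulated genes 200 were changed for the whole-worm table, and 53 of 214 for the unc-4 table. For the whole-worm table the fit recovered 78% of 4-fold and 99% of 16-fold changes, with 8 false calls among unchanged genes. For the unc-4 table it recovered 0% of 4-fold and 53.8% of 16-fold changes, with 0 false calls. In the real tables every gene was selected as higher and the groups differ in level, so these rates do not carry over to them.

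Of 31 gene lists fixed before the data were examined, members were matched by identifier. The planned Fisher's exact test of list members against the other genes of a table had no content, because every gene of a table was called and in the same direction. In its place, chosen after the data were seen, the listed share of each list in the whole-worm table was set against the pooled members of the muscle, pharynx, intestine, hypodermis and germline lists, and the share of list members among unc-4 genes against that among whole-worm genes, with the 13 shared genes left out. Both used 2-sided Fisher's exact tests adjusted by Benjamini-Hochberg. Annotated members include genes that may not have been expressed or tested, so shares describe the lists and not the tested background. Counts adjusted over a list alone were not possible without p-values of unlisted genes. The overlap of the tables was set against all 19985 annotated protein-coding genes. Both tables share the wild type libraries, and chance overlap under shared controls was not simulated because unlisted genes are not analysed here.

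Genes named in the text are, per table, the 12 with the largest authors' fold among those with a mean of at least 5 TPM in the higher group and every library of that group above every library of the other, up to 4 listed members with the largest fold in each list, and 12 names fixed beforehand (unc-4, unc-37, unc-3, unc-17, ceh-12, acr-5, del-1, glr-4, mab-9, pde-1, unc-7 and unc-9). The study is known to have chosen pde-1 from these libraries, so its value is not independent evidence. Other names were chosen after their values were seen and are marked as such. Values are means ± SD over 3 libraries unless given per library. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Alternatives were stricter FDR and fold thresholds, other filters on low values, a pseudocount of 0.1, each library left out, which was also applied to the ratios of named genes after the data were seen, and the replicate number as a block.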

Results

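Transcript levels were compared between sorted wild type VA motor neurons and whole L2 worms, and between VA neurons of unc-4 mutants and of wild type, with 3 libraries in each group. UNC-4 is a homeodomain transcription factor that acts with the Groucho-like corepressor UNC-37 in these neurons. Only genes that the authors called higher in VA neurons, or higher in the mutant, were at hand, with a TPM value per library and no sequencing depth.

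The first comparison asks which transcripts are enriched in the sorted wild type VA libraries. The gate also takes AVF neurons, so a listed gene may come from other sorted cells, and the cell of origin was not tested. Genes that mark cholinergic ventral cord motor neurons were far above whole worms. Transcripts of unc-4 (WBGene00006744, chromosome II, 9897751 to 9900376) averaged 1126 ± 187 TPM (SD, n = 3) in VA neurons and 12.8 ± 1.70 TPM (n = 3) in whole worms, a ratio of 88.1. Cells were sorted on reporters driven by parts of the unc-4 promoter, so this level is no independent check of their identity. The COE-type factor unc-3 (X, 14773538 to 14783568) averaged 703 ± 238 against 9.91 ± 2.60 TPM, and the zinc finger gene bnc-1 (V, 12275570 to 12277046) 977 ± 176 against 19.5 ± 6.22 TPM. The vesicular acetylcholine transporter gene unc-17 averaged 259 ± 95.3 against 2.63 ± 0.897 TPM, and the choline acetyltransferase gene cha-1 108 ± 16.5 against 6.54 ± 1.26 TPM. These genes overlap on chromosome IV (3618259 to 3624699 and 3613931 to 3624697), so reads shared between them make each value uncertain. The corepressor gene unc-37 averaged 60.7 ± 17.8 against 19.97 ± 4.14 TPM.

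**Figure D1:**
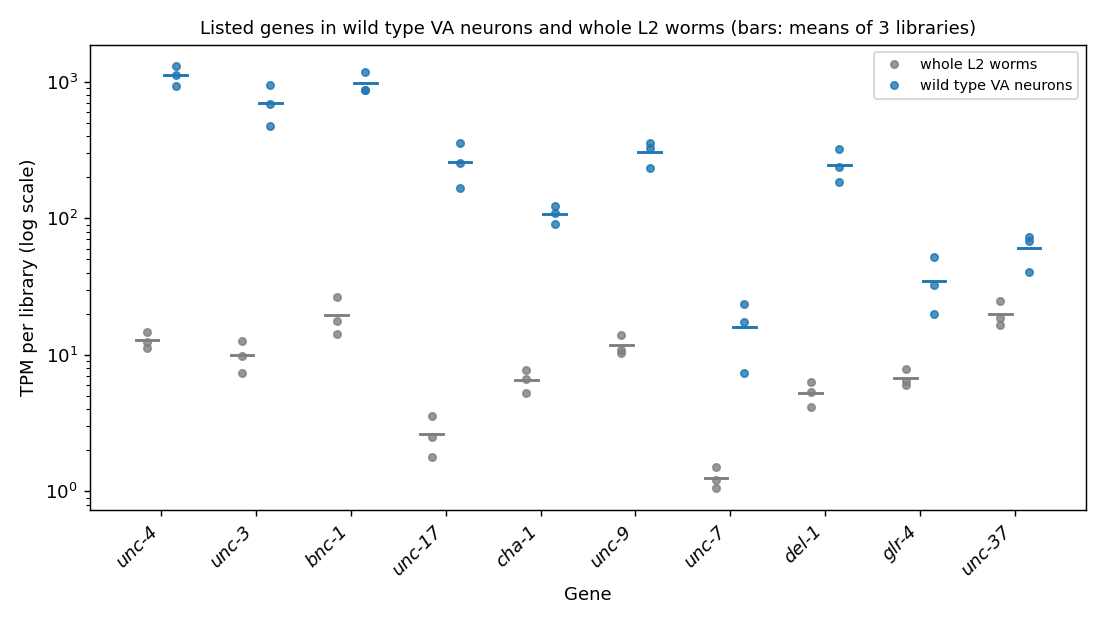
TPM per library on a log axis for 10 named genes in wild type VA neurons (blue) and whole L2 worms (gray), with points for the 3 libraries of each group and bars for their means. Every VA library lies above every whole-worm library for each gene shown, with mean ratios from 3.04 for unc-37 to 98.6 for unc-17.

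In total 2349 genes were listed as higher in wild type VA neurons, of which 2313 are annotated as protein coding. The authors' deposited table gives folds from 2.25 to 3009 with a median of 6.94. In 2158 genes (91.9%) every VA library was above every whole-worm library, where chance separates 5% of unselected genes in this direction at 3 against 3 (10% in either direction); these genes were selected on the same libraries, so the share tests nothing. The listed genes took up 50.3% ± 7.95 (SD, n = 3) of all TPM in VA neurons and 4.70% ± 0.332 (n = 3) in whole worms. On log2(TPM + 1), limma's test passed 2214 of 2328 listed genes at an adjusted p under 0.05, and unc-4 differed by 6.35 ± 0.32 (SE, adjusted p = 2.6e-07 by limma).

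Of 26 lists tested against pooled lists of other tissues, 21 had a higher listed share at an adjusted p under 0.05 (Fisher's exact test). Members of the pooled lists were listed in 11 of 343 cases (3.21%). Whole worms contain those tissues, so the reference itself favoured a low share of their genes and small p-values for neuronal lists. Of all annotated protein-coding genes, 11.6% were listed. Ciliated neuron markers (adjusted p = 0.63) and glutamate and monoamine neuron markers (adjusted p = 1) were among the 5 that did not pass. Of 34 genes of synaptic vesicle release and other pan-neuronal functions, 32 were listed (Fisher's exact test, adjusted p = 2.9e-33), among them sad-1, rimb-1, cpx-1 and sng-1, with mean TPM ratios of 36.2, 23.7, 19.97 and 19.8. Cholinergic genes were listed in 6 of 9 cases (adjusted p = 8.2e-07), which besides unc-17 and cha-1 included the choline transporter gene cho-1 at 132 ± 61.1 against 3.03 ± 0.393 TPM and ace-3 at 48.8 ± 24.7 against 4.49 ± 0.794 TPM. Motor neuron transcription factors were listed in 12 of 20 cases (adjusted p = 4.8e-11), including pag-3 at 23.6 ± 14.4 against 0.907 ± 0.373 TPM. Homeobox genes were listed in 23 of 93 cases (adjusted p = 3.7e-09), with zag-1 at 319 ± 25.99 against 6.25 ± 1.498 TPM, ceh-5 at 10.1 ± 0.972 against 0.371 ± 0.141 TPM and ceh-86 at 8.11 ± 4.76 against 0.259 ± 0.254 TPM.

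Channel and receptor lists had raised shares of listed members. Potassium channel genes were listed in 30 of 71 cases (adjusted p = 1.4e-16). The tandem pore channel genes twk-39, twk-40, twk-7 and twk-30 had mean TPM ratios of 196, 68.6, 46.3 and 45.2. Nicotinic-type receptor genes were listed in 11 of 31 cases (adjusted p = 1.8e-07), with acr-2 at 447 ± 189 against 13.9 ± 3.97 TPM, acr-12 at 247 ± 80.0 against 10.01 ± 3.25 TPM, and ratios of 28.9 for acr-19 and 24.3 for acr-14. Glutamate receptor genes were listed in 8 of 21 cases (adjusted p = 2.6e-06), with ratios of 63.9 for the auxiliary subunit gene sol-2, 10.03 for mgl-3, 9.10 for glc-3 and 6.14 for avr-14. Amine and muscarinic receptor genes were listed in 14 of 24 cases (adjusted p = 3.9e-12), with ratios of 30.7 for dop-1, 17.95 for octr-1, 17.7 for ser-3 and 16.7 for gar-2.

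Neuropeptide precursor genes were listed in 35 of 145 cases (adjusted p = 3.5e-11). The FMRFamide-like gene flp-1 reached 62369, 21477 and 118785 TPM in VA replicates 1, 2 and 3 against a mean of 334 ± 11.1 TPM in whole worms, and H05L03.3, now nlp-49, averaged 24105 ± 12372 against 178 ± 37.7 TPM. Over the same VA libraries unc-4 read 1311, 936 and 1129 TPM, so flp-1 varied more, and which sorted cells held flp-1 was not tested. The precursor gene nlp-14 had a ratio of 48.8, and nlp-19 read 121, 19.3 and 63.1 TPM in VA replicates 1 to 3 against 0, 0.736 and 1.02 TPM in whole-worm replicates 2 to 4. Peptide receptor genes were listed in 51 of 98 cases (adjusted p = 1.6e-27), with ratios of 87.8 for frpr-14, 52.1 for gnrr-1, 35.8 for dmsr-5 (62.2 without whole-worm replicate 2) and 33.4 for frpr-3. Guidance and adhesion genes were listed in 31 of 68 cases (adjusted p = 6.6e-18), including ratios of 410 for zig-2, 33.01 for oig-5, 27.4 for the netrin gene unc-6 and 26.1 for efn-4.

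Signalling and transport lists also had raised shares. Genes of the cAMP signalling list were listed in 14 of 20 cases (Fisher's exact test, adjusted p = 1.2e-13). That list also holds other signalling genes, such as the diacylglycerol kinase gene dgk-1 with a ratio of 26.4. Further ratios were 11.5 for epac-1, 9.74 for the G protein gene goa-1 and 9.60 for pde-3, while pde-1 was not listed. Wnt signalling genes were listed in 13 of 28 cases (adjusted p = 5.3e-10), with ratios of 15.9 for lin-17, 13.9 for sfrp-1, 13.7 for mig-1 and 9.72 for cwn-1. Microtubule motor genes were listed in 10 of 32 cases (adjusted p = 1.7e-06), with ratios of 14.5 for jip-1, 7.06 for lis-1, 6.04 for klp-7 and 5.90 for klp-20. The gap junction genes unc-9 (305 ± 64.4 against 11.7 ± 2.06 TPM) and unc-7 (16.03 ± 8.13 against 1.25 ± 0.226 TPM) were listed with inx-1 and inx-19, which makes 4 of 25 innexins (adjusted p = 0.019). Degenerin-type channel genes were listed in 4 of 30 cases (adjusted p = 0.031), namely del-1 at 248 ± 70.4 against 5.29 ± 1.12 TPM, del-8, asic-1 and unc-8. Of 5 genes that earlier work placed under UNC-4 repression, del-1 and glr-4 (34.7 ± 16.1 against 6.79 ± 1.01 TPM) were listed (adjusted p = 0.017), and ceh-12, acr-5 and mab-9 were not. With all other protein-coding genes as comparator, the calls of the innexins, the degenerin-type channels and these repressed genes were lost (adjusted p = 0.65, 0.83 and 0.17).

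**Figure D2:**
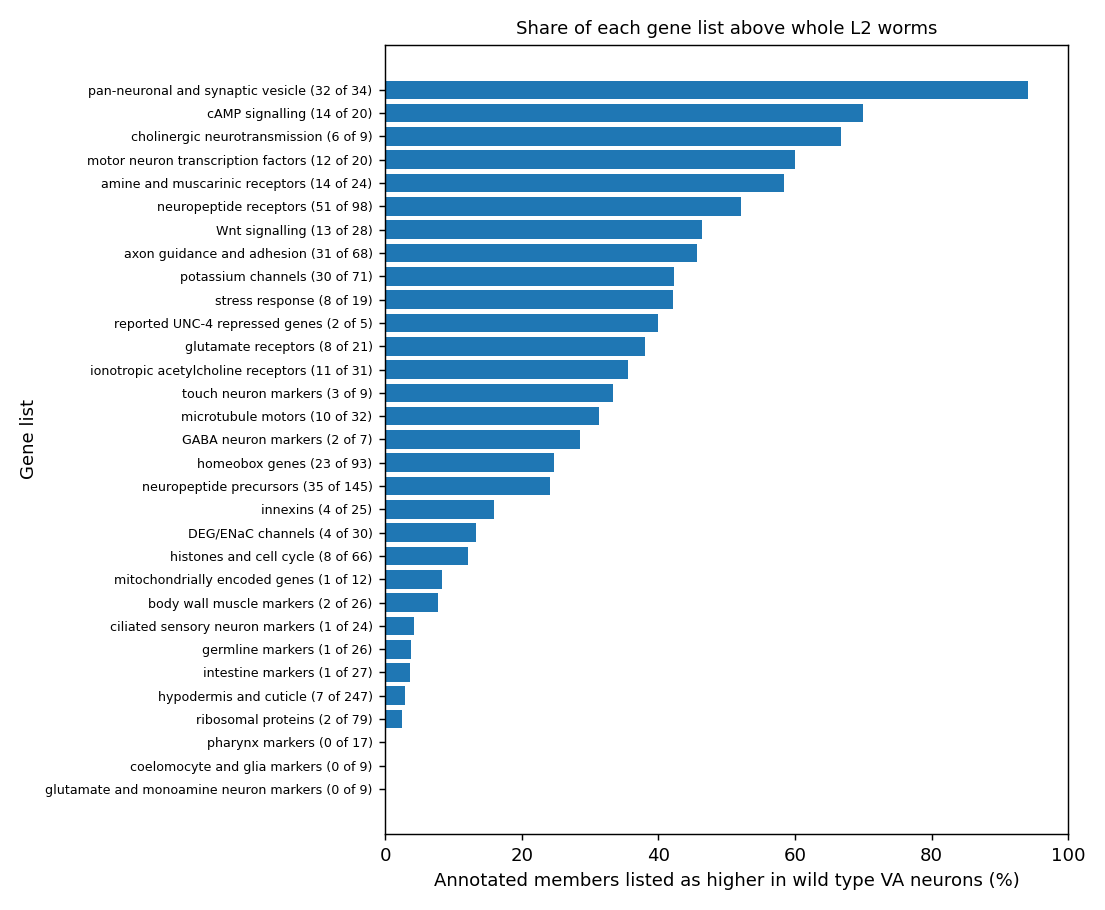
Bars give the percent of annotated members of each of 31 gene lists that were listed as higher in wild type VA neurons, with listed and annotated members in parentheses. The pan-neuronal list has the highest share, 94.1%, and the pharynx, coelomocyte and glia, and glutamate and monoamine neuron lists are at 0%.

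Markers of other cells were mostly missing from the listed genes. Genes were listed only when above whole worms, which contain these cells. RNA of other cells at or below its whole-worm level would not appear, so the missing markers do not measure the purity of the sort. Glutamate and monoamine neuron markers (0 of 9), coelomocyte and glia markers (0 of 9), pharynx markers (0 of 17), ciliated neuron markers (1 of 24, daf-19), intestine markers (1 of 27, fat-7, at most 2.50 TPM) and germline markers (1 of 26, wago-1) had few listed members or none. Muscle markers were listed in 2 of 26 cases, unc-97 and pat-3, with ratios of 2.01 and 1.95. Touch neuron markers were listed in 3 of 9 cases (adjusted p = 0.0060), the tubulin genes mec-12 (6708 ± 2573 against 437 ± 83.1 TPM) and mec-7 and the stomatin-like gene mec-2. GABA neuron markers were listed in 2 of 7 cases (adjusted p = 0.031), snf-11 at 127 ± 49.5 against 14.98 ± 5.29 TPM, a gene also reported in AVF, and unc-55. The latter averaged 16.8 TPM in VA neurons but read 0.0256 TPM in VA replicate 3, under the 1.34, 1.05 and 2.63 TPM of whole-worm replicates 2 to 4, and was not separated. Both calls were lost with all other protein-coding genes as comparator (adjusted p = 0.13 and 0.29). Hypodermis and cuticle genes were listed in 7 of 247 cases, led by grl-8 at 318 ± 206 against 2.63 ± 0.430 TPM and grl-9 with a ratio of 32.3; of the collagen genes col-152 and col-137, the latter read 0, 9.63 and 0 TPM in VA replicates 1, 2 and 3. Histone and cell cycle genes were listed in 8 of 66 cases (adjusted p = 0.0080, and 0.88 against all other protein-coding genes), with ratios of 7.03 for cdk-4, 7.02 for his-24, 4.12 for his-72 and 3.29 for his-74 (2.10 without VA replicate 1). Ribosomal protein genes (2 of 79, rps-12 and rpl-42) and mitochondrially encoded genes (1 of 12, ctc-3, ratio 2.14) did not pass the test against other tissues (adjusted p = 1 and 0.40). Of the genes named in this paragraph, unc-55, fat-7, col-137, col-152, ctc-3 and rps-12 missed the threshold of limma's test (adjusted p = 0.11, 0.17, 0.22, 0.094, 0.069 and 0.078).

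Heat shock genes were high in the sorted neurons and unequal between the libraries. Stress genes were listed in 8 of 19 cases (adjusted p = 1.3e-06). Together they made up 2.70%, 12.5% and 1.41% of TPM in VA replicates 1, 2 and 3, and 0.239%, 0.0729% and 0.0898% in whole-worm replicates 2, 3 and 4. Within the list the most expressed was hsp-16.49 at 10558, 45509 and 8347 TPM in VA replicates 1 to 3, followed by hsp-16.11, with hsp-16.41 and hsp-70 at ratios of 56.5 and 131. Without VA replicate 2 these ratios were 24.2 and 32.9, and without whole-worm replicate 2 that of hsp-16.41 was 97.5. Outside the list, F44E5.4 and F44E5.5, Hsp70-family genes chosen after their values were seen, took a further 20.04% of TPM in VA replicate 2. The hsp-16 genes include near-identical copies, so their single values are uncertain. As TPM shares a fixed total, these shares together lower other genes in VA replicate 2, and without that library limma's test passed 2132 genes.

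Of the 12 largest folds among separated genes with a mean of at least 5 TPM in VA neurons, 4 belonged to genes without signal in whole worms. R13G10.4, C17D12.5, C45G9.8 and cal-6 were listed at 0 in all 3 whole-worm libraries, so no ratio is given, and R13G10.4 read 1.71, 14.6 and 0.0265 TPM in VA replicates 1 to 3. At higher levels stood lin-15B (3820 ± 1963 against 4.64 ± 0.843 TPM) and lin-15A (2041 ± 1013 against 2.29 ± 1.31 TPM), which overlap on chromosome X (15726123 to 15732025 and 15731968 to 15735365), and F26C11.3 (93.5 ± 50.4 against 0.101 ± 0.0120 TPM), the next gene upstream of unc-4 on chromosome II (9903057 to 9915099). The bHLH gene hlh-34 averaged 76.8 ± 54.9 against 0.156 ± 0.0745 TPM. K08C9.1, F54F7.6, dct-10 and the immunoglobulin-domain gene zig-2 (3040 ± 1888 against 7.41 ± 1.38 TPM) completed the 12.

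The second comparison asks which transcripts rise in VA neurons that lack UNC-4 function. The VB motor neuron homeobox gene ceh-12 (WBGene00000436, chromosome I, 5840282 to 5841940), reported earlier as an UNC-4 target, read 40.2, 139 and 85.5 TPM in unc-4 replicates 1, 2 and 3 and 0.620, 0.498 and 1.11 TPM in wild type replicates 1 to 3. Its mean ratio was 118.9. On log2(TPM + 1) it differed by 5.52 ± 0.88 (SE, adjusted p = 0.0047 by limma). That call was lost in limma's test without wild type replicate 2 (adjusted p = 0.053) or unc-4 replicate 3 (adjusted p = 0.072). The mean ratio of ceh-12 was then 102 or 121, and it lay between 84.8 and 158 with any library left out. Of the other reported targets, del-1, glr-4, acr-5 and mab-9 were not listed, and neither were unc-37, unc-3, unc-17, unc-7 or unc-9. As unc-4 itself was not listed, its transcript gives no check of the genotype labels here.

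Altogether 214 genes were listed as higher in unc-4 VA neurons, with folds from 3.69 to 311 and a median of 13.3 in the authors' deposited table. In 150 of them (70.1%) every unc-4 library was above every wild type library, a share that the selection on these libraries sets and that the chance share of unselected genes, 5% in this direction and 10% in either, cannot test. They made up 4.81% ± 2.63 (SD, n = 3) of TPM in unc-4 and 0.389% ± 0.104 (n = 3) in wild type VA neurons. The unc-4 libraries were unequal: 6.37%, 1.77% and 6.28% of TPM in replicates 1, 2 and 3. Replicate 2 was the lowest unc-4 library in 178 genes and did not exceed the highest wild type library in 59. On log2(TPM + 1), limma's test passed 173 of 214 genes at an adjusted p under 0.05, and 211 without unc-4 replicate 2. Leaving out another library left 0 genes (unc-4 replicate 3, with 102 at an unadjusted p under 0.05), 42 (unc-4 replicate 1), 2 (wild type replicate 1), 1 (wild type replicate 2) or 14 (wild type replicate 3), so most adjusted calls were lost without any library other than unc-4 replicate 2, and all 173 were kept without that one. Ratios of mean TPM also depended on single libraries, and those of 33 of 41 named genes moved by over 1.5 times with 1 library left out.

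Neuropeptide precursor genes had 13 members listed in the mutant table. Leaving out genes shared by both tables, they made up 12 of 201 mutant genes (5.97%) and 34 of 2336 whole-worm genes (1.46%, Fisher's exact test, adjusted p = 0.0048), the only 1 of 31 lists past the threshold. Whether these genes rose within VA neurons or came from other sorted cells was not tested. The FMRFamide-like gene flp-9 averaged 7719 ± 2254 against 384 ± 157 TPM. The genes flp-15 (2318, 174 and 4048 TPM in unc-4 replicates 1 to 3, wild type mean 72.4 ± 8.67 TPM) and nlp-12 (2017, 118 and 3621 TPM, wild type mean 31.6 ± 4.83 TPM) were far lower in replicate 2. So were Y67D8B.4, now nlp-81 (115.3, 8.74 and 234.6 TPM, ratio 23.3, and 12.1 without replicate 3), and, outside the list, Y23B4A.2, now capa-1 (1895, 44.1 and 783 TPM, ratio 67.1, and 30.6 without replicate 1). Peptide receptor genes were listed in 6 cases (adjusted p = 1), with ratios of 11.9 for frpr-15 (7.37 without unc-4 replicate 1), 10.1 for npr-28, and 9.11 for frpr-17 and 8.93 for the cholecystokinin-like receptor gene ckr-1 (14.6 and 14.1 without wild type replicate 1).

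Homeobox genes were listed in 8 cases and made up 3.48% of mutant genes against 0.942% of whole-worm genes, which missed the threshold (adjusted p = 0.065). Besides ceh-12 these were led by ceh-24 (148, 9.17 and 356 TPM in unc-4 replicates 1 to 3, wild type mean 4.41 ± 3.31 TPM), ceh-31 (ratio 28.5, and 60.5 without wild type replicate 1) and lim-4 (632, 28.7 and 1180 TPM against 46.8, 2.20 and 35.1 TPM in wild type replicates 1 to 3), the last 2 without separation of the groups. The GABA motor neuron gene unc-30, the only GABA marker and with ceh-12 the only motor neuron factor listed (adjusted p = 0.76 and 0.86), averaged 88.7 ± 41.7 against 10.1 ± 3.69 TPM.

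**Figure D3:**
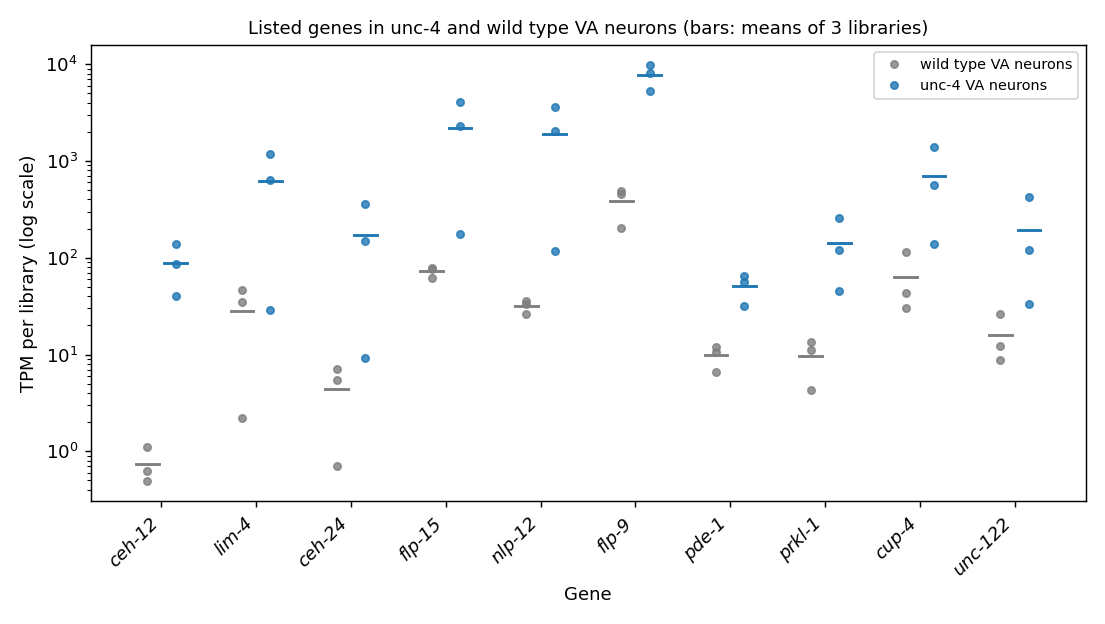
TPM per library on a log axis for 10 named genes in unc-4 (blue) and wild type (gray) VA neurons, with points for the 3 libraries of each group and bars for their means. For ceh-12 all unc-4 libraries lie above 40 TPM and all wild type libraries at or below 1.11 TPM, while for flp-15 and nlp-12 unc-4 replicate 2, at 174 and 118 TPM, lies far below the other unc-4 libraries.

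Other lists had single members or small groups in the mutant table, none past the threshold. The phosphodiesterase gene pde-1, chosen by the study from these libraries, averaged 51.0 ± 17.6 against 9.78 ± 2.79 TPM, a ratio of 5.22 and the only cAMP gene listed (adjusted p = 1). The Prickle gene prkl-1 averaged 142 ± 108 against 9.56 ± 4.69 TPM (Wnt list, adjusted p = 1), the kinesin-like gene vab-8 244 ± 95.9 against 29.7 ± 14.1 TPM (motor list, adjusted p = 1) and the acetylcholinesterase gene ace-1 7.07 ± 7.03 against 0.343 ± 0.267 TPM (cholinergic list, adjusted p = 1). Leaving out unc-4 replicate 3 lowered the ratio of prkl-1 from 14.9 to 8.73 and that of ace-1 from 20.6 to 8.80. Without wild type replicate 1 the ratio of ace-1 was 33.2. Guidance and adhesion genes were listed in 5 cases (adjusted p = 0.76), with ratios of 29.3 for zig-4, 11.9 for dig-1, 10.7 for lad-2 and 8.13 for zig-5. Without unc-4 replicate 1 the ratios of zig-4 and dig-1 were 8.60 and 6.26, and without replicate 3 those of lad-2 and zig-5 were 5.93 and 4.99. In this group zig-4, dig-1 and zig-5 were not separated, and dig-1 and zig-5 missed the threshold of limma's test (adjusted p = 0.051 and 0.10). The receptor genes acr-15 and acr-16 (adjusted p = 0.85), ser-5 and tyra-2 (adjusted p = 0.94) and glr-2 (adjusted p = 1) and the potassium channel gene C32C4.1, now kvs-2 (adjusted p = 1), were listed with ratios of 5.82, 19.6, 18.3, 9.46, 11.9 and 6.98. Without unc-4 replicate 3 those of acr-16, ser-5 and tyra-2 were 11.97, 10.7 and 4.34, and without wild type replicate 1 those of ser-5 and C32C4.1 were 30.65 and 10.5. Of these genes acr-16 and tyra-2 were not separated and missed the threshold of limma's test (adjusted p = 0.091 and 0.093). Reported UNC-4 repressed genes, with ceh-12 alone, gave an adjusted p of 0.76. For 12 lists no member was listed: innexins, pan-neuronal, degenerin-type channels, ciliated, touch, glutamate and monoamine neurons, muscle, germline, stress, histones, ribosomal and mitochondrial genes.

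Markers of other cells appeared among the mutant genes. The coelomocyte genes cup-4 (1409, 140 and 567 TPM in unc-4 replicates 1 to 3) and unc-122 (422, 33.3 and 118.8 TPM) were listed, 2 of 9 members of the coelomocyte and glia list against 0 whole-worm genes (adjusted p = 0.065). Their wild type means were 62.8 ± 45.9 and 15.8 ± 9.34 TPM. Among unc-4 libraries both were lowest in replicate 2, as were flp-15, nlp-12, ceh-24, lim-4 and flp-9 (5270 TPM), while ceh-12 was highest there. Pharynx, intestine and hypodermis lists had 1 listed member each, phat-5, lys-1 and col-129 (adjusted p = 0.61, 0.76 and 1). Among separated genes with a mean of at least 5 TPM, the 12 largest folds, besides ceh-12, nlp-12, Y23B4A.2 and col-129, were those of Y47D7A.12, zip-8, gcy-11, scl-14, gcl-1, F11E6.6, ces-1 and srh-271, with unc-4 means from 5.15 to 173 TPM. Of these F11E6.6 and srh-271 missed the threshold of limma's test (adjusted p = 0.069 and 0.053).

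Of the listed genes, 13 appeared in both tables, where independent lists of these sizes among 19985 protein-coding genes would share 24.7 (2-sided Fisher's exact test, p = 0.0095). They include lim-4, nlp-15, nlp-38, npr-12, lgc-28 and the adhesion genes wrk-1 and unc-71, the last 6 chosen after their values were seen. Wild type VA libraries are the higher group in the first table and the lower group in the second, so shared chance pushes the overlap down.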

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

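The limma fits to listed genes, the list comparators and the separation counts were chosen after the data were seen. The counts of 2349 and 214 listed genes stayed within 1.5 times under each threshold and filter tried (FDR under 0.01, at least 2-fold, at least 4-fold, mean of at least 5 TPM), with lowest values of 1720 at 4-fold and 146 at an FDR under 0.01. The smallest listed folds were 2.25 and 3.69, so the 2-fold setting could remove no gene and shows nothing about stability. At 4-fold 213 genes of the unc-4 table stayed, which its selection largely fixed. The overlap fell from 13 to 4 genes at an FDR under 0.01, where shorter lists enter (13.9 by independence). Lists past the threshold numbered 22 over both tables, 18 without the hypodermis list in the comparator and 17 against all other protein-coding genes, where 6 were lost and ribosomal proteins entered with a lower share (adjusted p = 0.013). Genes past limma's test ranged from 1899 to 2248 with a library left out for the whole-worm table (main 2214) and from 0 to 211 for the unc-4 table (main 173); fewer samples enter, and why the counts were higher without unc-4 replicate 2 and without VA replicate 3 (2248) was not tested. Among 41 named genes of the unc-4 table, leaving out a library ended an adjusted call in 155 gene and library combinations, kept its side in 84 and gave a call in 7, with no change of sign. Among 101 of the whole-worm table, the sign changed once: col-137, uncalled, at 1.02 (log2), ranged from -0.12 without VA replicate 2, the library that holds its signal, to 1.59.

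No label says that the replicate numbers pair the samples. Deviations of same-numbered unc-4 and wild type libraries correlated at 0.02, 0.18 and 0.06 across genes, and those of different-numbered libraries at -0.13 to 0.095. Deviations within a group are tied to each other and the genes were selected, so these values cannot decide whether the samples are paired. With a replicate block, limma passed 185 genes of the unc-4 table and 1597 of the whole-worm table, where only numbers 2 and 3 are shared. Wild type replicate 3 has a library number next to those of the mutant. Its median distance to unc-4 was 2.84 (log2), between the 2.62 and 3.21 of replicates 1 and 2, and it was 0.51 from the other wild type libraries. These distances cover only genes listed as higher in unc-4 than in the wild type group, which includes that library. They therefore cannot show whether the order of the libraries matters. Not run were other scalings, which on genes all chosen in 1 direction would remove the difference itself, count-based fits, Bonferroni or unadjusted p-values, which the tables do not give, and set tests with an estimated correlation. Depth is unknown, so it sets no limit that can be stated.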

Other observations

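All tests in this part, and the genes it names outside the rule, were chosen after the results were seen. Neighbouring genes were counted among those listed as higher in unc-4 VA neurons. Among 213 protein-coding genes, 12 pairs were at most 2 positions apart, including acr-15 and acr-16 on chromosome V, C12D5.3, C12D5.4 and C12D5.5 on the same chromosome, and flp-18 and M02F4.1 on X. Random sets of the same size gave a median of 4 pairs from the annotation (1-sided permutation p = 9.0e-04, 10000 draws) but 7 from genes of the whole-worm table (p = 0.056), and the excess over the latter missed the threshold. The genes of 1 pair, Y73B6BL.47 and Y73B6BL.270, overlap. Chromosome X held 20.8% of the whole-worm genes and 19.7% of the mutant genes, against 13.7% of annotated protein-coding genes, which is a description and was not tested.

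A set of 13 genes was highest in unc-4 replicate 2, against the trend of that library. Besides ceh-12 these include the transcription factor genes vab-23 (43.0, 118 and 62.1 TPM in unc-4 replicates 1 to 3), hlh-32 (18.8, 155 and 28.5 TPM) and ces-1 (6.65, 10.4 and 0.791 TPM), and nlp-38 (128, 461 and 190 TPM).

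The genes lin-15A, lin-15B, let-858 and F26C11.3 were among those furthest above whole worms, and let-858 (10343, 7773 and 2809 TPM in VA replicates 1 to 3) was at 28.7 to 34.5 TPM in whole worms. Sequences of lin-15 and let-858 are common parts of worm transgenes, the sorted strain carries reporters with unc-4 promoter sequence and the whole worms do not, so a candidate explanation is reads from the transgenes. F26C11.3, whose 3' end lies 2681 bases upstream of unc-4, ranked 4 in fold among 2349 genes, but it was noticed by that rank, the labels do not give the transgenes' parts, and strain coincides with group, so transgene reads and expression from the genes' own loci cannot be told apart. A stress response to sorting was tested by the ratio of VA replicate 2 to 1, at most 1.23 for the 4 genes and 1.02 to 8.91 for the listed stress genes; the ratio of replicate 2 to 3 was 1.71 to 3.31 for the 4 genes and at least 1.501 for the stress genes. In both ratios hsp-1 alone was not above the 4 genes, and the other 7 stress genes were (at least 3.57 and 5.45), so most stress genes go against it, but the outcome turns on leaving out hsp-1 after its value was seen, and it stays open.

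Heat shock genes were high and unequal in sorted wild type neurons. Dissociation and sorting, which the frozen worms did not undergo, may have induced them. Their summed TPM in the lowest sorted library was 5.88 times that in the highest whole-worm library. Because genes were listed for being higher and handling coincides with group, handling and the biology of VA neurons cannot be told apart as sources of the raised level. The inequality, at 2.70%, 12.5% and 1.41% of TPM in VA replicates 1, 2 and 3, lies within a group of the same genotype and gate. The difference between the groups does not bear on it, and its source was not tested.

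In unc-4 VA replicate 2 most listed genes were low, at a median of 9.65% of the excess over wild type seen in replicates 1 and 3 (quartiles 1.43% and 38.1%). The tables argue against a wild type library under a wrong label: 155 of 214 genes were higher in it than in all 3 wild type libraries, where a further wild type library would give 53.5 by chance, although selection on this library raises that count, and ceh-12, fixed beforehand, read 139 TPM against at most 1.11. They also argue against coelomocyte RNA in replicates 1 and 3 as the only source, since 73 genes were over 1.5 times higher in replicate 3 than in replicate 1 while cup-4 and unc-122 were lower there. For those markers themselves coelomocyte RNA is a candidate source: both were at least 3.57 times higher in replicates 1 and 3 than in replicate 2 and in every wild type library, though the gate should exclude such cells and expression by mutant neurons would look alike. A difference in the share of mutant VA neurons or of other sorted cells, or between animals, stays open and untested.

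Other splits of the 6 libraries 3 against 3 were counted for limma's test. The real split gave the most genes in both tables, 1 of 10 splits in each, with 2214 and 173 genes and 0 as the highest of the others. With 10 splits the share cannot fall under 0.05, and the genes were selected for the real split, so nothing about chance follows.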
